A study of Mus musculus with 8 samples.

How the data were processed

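Single-cell RNA was sequenced from the immune fraction of subcutaneous B16 melanomas grown in C57BL/6 mice. Per the labels, each tumour was seeded with B16 cells that carried either a control guide RNA (control group) or a guide RNA against the kinase gene Tbk1 (TBK1 group). The labels give the same guide RNA for every library of a group. All mice received GVAX, an irradiated B16 cell vaccine that secretes GM-CSF, and an antibody against the checkpoint receptor PD-1. Cells bearing the leukocyte marker CD45 were enriched on magnetic beads and loaded on the 10x Genomics 3′ platform. The labels number 4 replicates per group and do not state in so many words that each is a separate animal. If each library is 1 mouse, the p values measure differences against the variation between mice, and otherwise they do not.

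The deposited files hold counts of unique molecular identifiers (UMI counts) per gene and cell barcode, made by the authors with Cell Ranger 3.0.1 on mm10, per the submitters' processing notes, and restricted to the barcodes that Cell Ranger called as cells. No normalization had been applied to the deposited counts. Each library came in a pair of copies with the same entries. The matrix and the barcodes of control replicate 1 were identical, value for value, to those of TBK1 replicate 1. The group of that shared matrix is therefore unknown, and by a choice made before the data were examined both labels were left out of every main comparison, which sets control replicates 2 to 4 against TBK1 replicates 2 to 4. The shared matrix was clustered with the others and its values are given apart. Raw reads were not used here.

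Barcodes with at least 300 detected genes and at most 10% mitochondrial UMIs were kept, which removed between 22.4% and 36.7% of the barcodes of a library. Doublet scores came from Scrublet as implemented in scanpy 1.11.5, and the highest-scoring barcodes were removed at 0.8% per 1000 barcodes of the library. Scrublet's own threshold was not used: it called 0 barcodes in control replicate 2 and in TBK1 replicate 4, and 0.131% of those in TBK1 replicate 3. Of 49402 barcodes in the 7 distinct matrices, 32807 cells remained, 26467 of them in the 6 libraries compared. Counts were scaled to 10000 UMIs per cell and logged, and 2000 variable genes, chosen within libraries, gave 30 principal components. Mitochondrial, ribosomal protein, immunoglobulin and T cell receptor genes and sex-linked genes were kept out of that choice. A graph of shared neighbours (15 per cell) was partitioned with leidenalg 0.10.2 at resolution 1, with no correction between libraries. Each of the 24 clusters took the name of the cell type whose fixed markers had the highest mean log2 ratio against all other cells, computed on CPM with 10 added. A name required at least 3 markers detected in 10% of the cells and at least 2-fold higher, a lead of 0.3 over the next type and no sign of mixed types, for instance Cd3e and Csf1r each in 25% of the cells. Clusters that failed stayed unnamed. Of the marker symbols 1 (Ahsp), and of the list symbols 6 (Mx2, Cxcl11, Ifi30, Cd244a, Aldoa and Atp5o), had no match in the 31053 genes. Gene positions are those of GENCODE M21 on GRCm38, the assembly also called mm10.

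For each of 11 named immune classes, the cells per library were tested with edgeR 4.0.16 (quasi-likelihood test, no trend of dispersion with abundance) against the total of named immune cells, with Benjamini-Hochberg adjustment over the 11 classes. For gene expression, UMIs were summed per library over all immune cells (unnamed immune clusters included) and over each of the 8 most numerous immune classes with at least 20 cells in every library. The sums were tested with edgeR (TMM, filterByExpr, quasi-likelihood F test) and adjusted over the genes of a sum, with a threshold of 0.05. Error terms of log2 fold changes are the estimate divided by the square root of F. Of 23 gene lists fixed beforehand, those with at least 5 tested members were compared with all other genes of a sum by limma 3.58.1 camera (log2 CPM, prior count 2, preset correlation between genes 0.01). They were type I interferon response, interferon gamma response, MHC class I presentation, MHC class II presentation, cytotoxic effector, T cell exhaustion, naive or memory T cell, regulatory T cell suppressive, proliferation, inflammatory (M1-type) macrophage, alternatively activated (M2-type) macrophage, complement and lipid-associated macrophage, hypoxia and glycolysis, NF-kappaB and TNF response, myeloid-recruiting chemokines, checkpoint ligands and co-stimulation, immediate early and heat shock, cell death, nuclear-encoded oxidative phosphorylation, and the RNA of melanoma pigment cells, erythroid cells, fibroblasts with endothelium, and neutrophils. Some genes stand in more than 1 list, such as Gzmb, Ciita and Cxcl10. Single values per library (class shares and cell ratios) were compared by exact two-sided permutation tests. With 3 libraries against 3 there are 10 splits, so the smallest exact p is 0.1.

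Genes are named by a rule fixed with the lists. In all immune cells up to 10 genes per direction, and in a class up to 4, were taken by absolute log2 fold change among those past the threshold with a mean of at least 20 CPM in a group and ranges that do not overlap. With fewer than 3 in a direction, the 2 of lowest unadjusted p were added as not passing. Each list past its threshold gives up to 4 passing members, or the 2 of lowest p. Tbk1, Ifng, Gzmb, Pdcd1, Cxcl9, Cxcl10, Arg1, Nos2, Mrc1 and Cd274 were followed wherever tested. Variable segments of antigen receptors, ribosomal protein and mitochondrial genes and unnamed gene models were counted and not named.

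The depth of a library ran from 20368071 to 39781312 UMIs. In an all-immune sum it ran from 9118766 to 19313862 UMIs, and in a plasmacytoid dendritic sum, the smallest, from 69381 to 106143. The tests were checked on simulated data, drawn per gene and independently from negative binomial distributions with the means, depths and dispersions of these libraries, in which 200 genes of a sum were changed. A 2-fold change was recovered for 67.3% of the changed genes in the all-immune sum, for 89.4% in CD8 T-like cells, for 56.7% in regulatory T-like cells and for 55.9% in plasmacytoid dendritic cells, and a 4-fold change for at least 96.9%. Of the genes called in a draw, 4.13% (plasmacytoid dendritic) to 8.46% (all-immune) were unchanged ones, over the nominal 5% in 4 of 5 sums. A list shifted 1.41-fold passed in 4 of 5 sums and was missed in plasmacytoid dendritic cells. A 2-fold change of a class share passed in 26% of the draws for regulatory T-like cells and in 25% for monocyte-like cells, and in only 13% for mature migratory dendritic cells, where a 4-fold change passed in 69%. Another class was called in 4.5% to 12% of the draws. Alternatives covered the shared matrix under either or both labels, each library left out, replicate number as a block, doublets kept, stricter and looser cell filters, Leiden resolutions of 0.6 and 1.5, other denominators and scalings, DESeq2 1.42.0, no filter on low counts, an estimated correlation between genes in camera, and limma's fry, which tests whether the genes of a list move on balance 1 way. With all 8 labels the same matrix enters both groups, so a call lost in that setting is partly built in. The looser mitochondrial limit, the counting of a granzyme-high cluster as CD8 T-like, the tests of single clusters and the tests in melanoma-like cells were added after the data were seen. Analyses ran in Python 3.11.15 and R 4.3.3.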

Results

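The series holds 8 single-cell libraries of CD45-enriched cells from B16 melanomas, 4 labelled control and 4 labelled TBK1, collected 13 days after implantation from mice given the GVAX vaccine and anti-PD-1. The series title sets out the question: how the immune cells of a treated tumour differ when the tumour cells carry a guide RNA against Tbk1, a kinase that relays signals from nucleic acid sensors to interferon genes. Because 1 matrix stands under both labels, as control replicate 1 and as TBK1 replicate 1, the comparisons set 3 control libraries against 3 TBK1 libraries. Control replicates 2, 3 and 4 held 26629845, 39129571 and 22865339 UMIs over 7421, 6821 and 6540 barcodes. TBK1 replicates 2, 3 and 4 held 28183005, 20368071 and 39781312 UMIs over 6316, 5557 and 7962 barcodes, and the shared matrix held 28665221 over 8785. After filtering, the 6 libraries kept between 3634 and 5118 cells each. In what follows, levels are CPM and shares are percent, both with SD over the 3 libraries of a group, log2 fold changes are TBK1 minus control with their standard error, and adjusted p values are from edgeR or limma.

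Most cells that passed the filter were immune, 24622 of 26467, and 21176 of these fell into clusters that could be named. The named classes were macrophage-like (C1qa, Ms4a7, Arg1, Mmp12), monocyte-like (Ly6c2, Chil3, Ace), CD8 T-like (Cd8a, Cd3g, Cxcr6), NK-like (Ncr1, Klrb1c, Gzma), regulatory T-like (Foxp3, Tnfrsf4, Ikzf2), plasmacytoid dendritic (Siglech, Ccr9), B-like (Ms4a1, Cd79a) and neutrophil-like (S100a8, S100a9). Conventional dendritic cells split into type 1 (Xcr1, Clec9a), type 2 (Cd209a, Mgl2) and mature migratory cells (Ccr7, Fscn1). A further 1787 cells were melanoma-like, with the pigment genes Dct, Pmel and Tyrp1. Their share of all cells was 6.96% ± 4.85 in the control group and 6.44% ± 1.23 in the TBK1 group (SD, n = 3). The 4 unnamed clusters made up 14.3% ± 2.19 and 13.7% ± 0.310 of the immune cells.

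Tbk1 (ENSMUSG00000020115, chromosome 10, 121546455 to 121586787, minus strand) was lower in the melanoma-like cells of each TBK1 library than in those of each control library. In control replicates 2, 3 and 4 its level was 21.2, 20.4 and 20.7 CPM, with 95% exact Poisson intervals of 16.8 to 26.4, 17.9 to 23.2 and 15.6 to 26.9. TBK1 replicates 2, 3 and 4 gave 8.97, 7.75 and 5.35 CPM, with intervals of 6.83 to 11.6, 5.33 to 10.9 and 3.70 to 7.47. These intervals cover counting error only. In a test added after these values were seen, Tbk1 fell from 20.8 ± 0.512 to 7.33 ± 1.75 CPM in melanoma-like cells (log2 fold change -1.498 ± 0.17, adjusted p = 0.000972). The immune cells come from hosts that were not edited. Their Tbk1 level was 43.3, 30.7 and 36.2 CPM in control replicates 2, 3 and 4, and 35.1, 34.7 and 46.4 CPM in TBK1 replicates 2, 3 and 4, a log2 fold change of 0.10 ± 0.18 (adjusted p = 1.00). That fold change was -0.01 without control replicate 3 and -0.12 without TBK1 replicate 4. In the shared matrix Tbk1 stood at 8.04 CPM in melanoma-like cells (5.93 to 10.7, 48 of 5969356 UMIs) and at 38.7 CPM in immune cells, and no group was assigned from these values. A guide RNA that disrupts a coding frame need not lower the 3′ tag of the transcript.

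**Figure D1:**
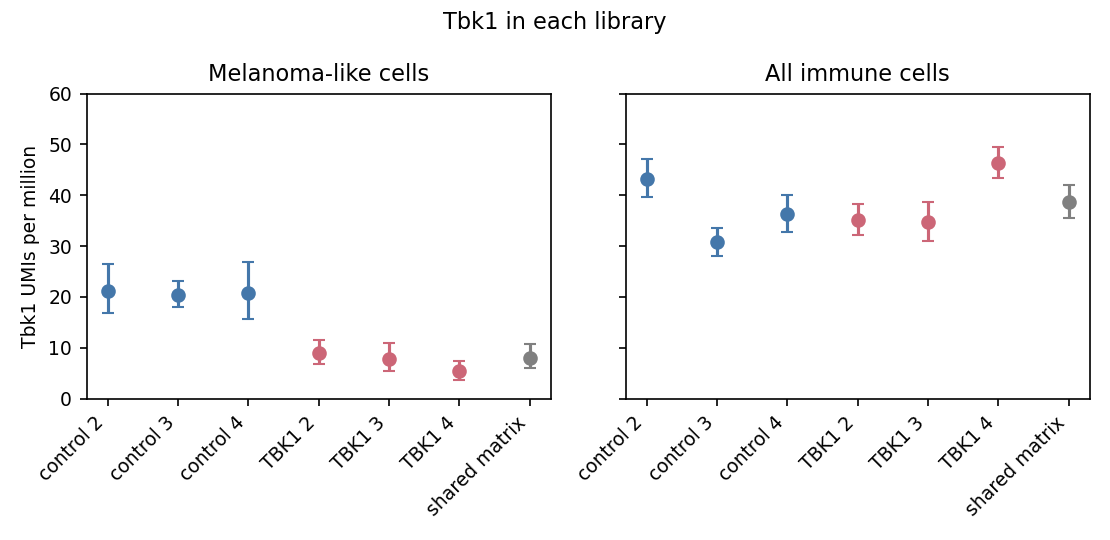
Tbk1 level (vertical axis, CPM) in melanoma-like cells and in all immune cells, 1 point per library with its 95% exact Poisson interval. The 3 TBK1 libraries lie between 5.35 and 8.97 in melanoma-like cells, under the 3 control libraries at 20.4 to 21.2, and the groups overlap in immune cells.

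The immune makeup was set mainly by myeloid and CD8 T-like cells in both groups, and none of the 11 classes differed in share past the threshold. Mature migratory dendritic cells, which carry antigen to lymph nodes, made up 1.01% ± 0.162 of named immune cells in the control group and 0.406% ± 0.202 in the TBK1 group (log2 fold change -1.29 ± 0.41, n = 3 per group), with non-overlapping ranges. Monocyte-like cells stood at 34.6% ± 7.03 and 24.6% ± 1.60 (-0.49 ± 0.30), also without overlap. Their ranges did overlap in other settings, among them doublets kept (-0.36, exact p = 0.2), Leiden resolution 0.6 and the 20% mitochondrial limit. Over all alternatives the estimate ran from -0.64 to -0.26, nearest 0 with TMM factors over the classes, and never passed. Macrophage-like cells stood at 28.2% ± 5.47 and 34.5% ± 9.00, and CD8 T-like cells, the main cytotoxic lymphocytes, at 20.2% ± 3.48 and 23.8% ± 9.81. TBK1 replicates 2 and 3 held 29.3% and 29.6% CD8 T-like cells, above each control library (16.6% to 23.6%), and TBK1 replicate 4 held 12.4%, below each. Without 1 library the log2 fold change ran from 0.04 to 0.54 for CD8 T-like and from 0.06 to 0.46 for macrophage-like cells, the values without TBK1 replicate 4 being 0.54 and 0.06. NK-like cells stood at 4.33% ± 1.36 and 5.20% ± 0.0732, and Foxp3-bearing regulatory T-like cells, which restrain other T cells, at 3.13% ± 0.183 and 2.50% ± 0.657. Neutrophil-like cells averaged 0.134% ± 0.0288 and 1.14% ± 1.53, and TBK1 replicate 4 alone held 2.91% against 0.299% and 0.207% in TBK1 replicates 2 and 3. In edgeR, 0 of 11 classes passed, and 2 had an unadjusted p under 0.05, mature migratory dendritic and neutrophil-like cells (adjusted p = 0.0545 for each). The exact permutation p was 0.1, the smallest possible, for neutrophil-like, mature migratory dendritic and monocyte-like cells, and between 0.2 and 0.6 for the others. Without TBK1 replicate 4 the mature migratory dendritic share passed (log2 fold change -1.78, adjusted p = 0.00876) and without TBK1 replicate 2 the neutrophil-like share passed (3.53, adjusted p = 1.66e-05). Without TBK1 replicate 4 the neutrophil-like log2 fold change was 0.92 (adjusted p = 0.192). Over all alternatives the adjusted p of these shares ran from 0.00876 to 0.525 and from 1.66e-05 to 0.383. Both shares rest on few cells. Mature migratory dendritic cells numbered 42, 31 and 32 in control and 8, 11 and 26 in TBK1 replicates 2, 3 and 4. Neutrophil-like cells numbered 4, 6 and 4 in those control libraries and 11, 6 and 122 in those TBK1 libraries.

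**Figure D2:**
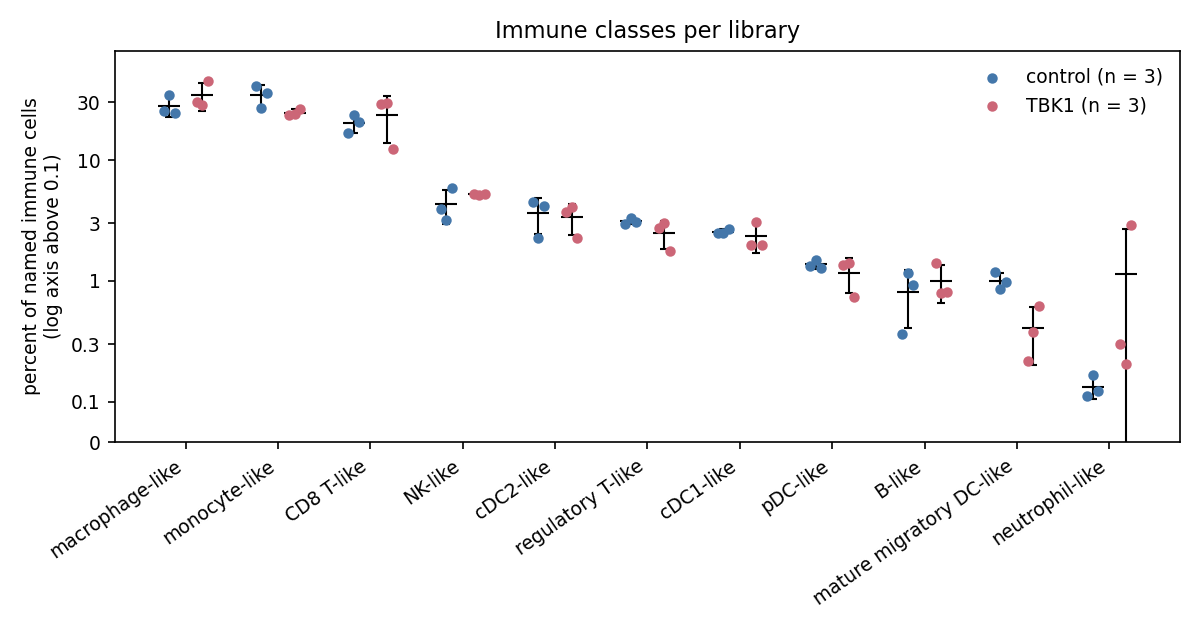
Share of each immune class (vertical axes, percent of named immune cells) in control and TBK1 libraries, 1 point per library, with the mean and SD of each group as a bar and line. The SD line of the TBK1 neutrophil-like share would run under 0 and is clipped there; monocyte-like and mature migratory dendritic cells show the control points (means 34.6% and 1.01%) above the TBK1 points (24.6% and 0.406%).

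Ratios of cell types that are customary in checkpoint blockade studies leaned the same way in means and did not pass an exact test. CD8 T-like cells numbered 6.44 ± 0.772 per regulatory T-like cell in the control group and 9.18 ± 1.89 in the TBK1 group (SD, n = 3), a difference of 0.50 in log2 ratio (exact p = 0.2; 0.37 to 0.68 over all alternatives). Macrophage-like cells were 45.05% ± 9.61 of macrophage-like and monocyte-like cells together in the control group and 57.8% ± 4.59 in the TBK1 group, a difference of 12.8 percentage points (exact p = 0.2). Over all alternatives this difference ran from 6.66 points, with doublets kept, to 18.3 without control replicate 3, and with replicate number as a block the exact p was 0.5. TBK1 replicate 4 was the highest for this share, at 62.9%, and the lowest of its group for the ratio of CD8 T-like to regulatory T-like cells, at 7.05. In the shared matrix the values were 6.61 and 46.8%.

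Across all immune cells summed, no single gene passed the test, while several gene lists leaned to 1 side. Chil3, a chitinase-like protein made by monocytes, stood at 200 ± 48.0 CPM in the control group and 106 ± 9.98 in the TBK1 group (log2 fold change -0.91 ± 0.17, n = 3 per group). Fdps, farnesyl diphosphate synthase of the sterol pathway, stood at 36.0 ± 3.33 and 22.3 ± 0.901 (-0.69 ± 0.10). On the other side were Slc7a2, an arginine transporter, at 17.5 ± 0.338 and 27.8 ± 2.76 (0.67 ± 0.11), and Ly9, a SLAM-family receptor of lymphocytes, at 35.7 ± 1.63 and 50.3 ± 4.22 (0.50 ± 0.10). None of these passed in edgeR (adjusted p = 1.00), which called 0 of 11880 genes, with 270 at an unadjusted p under 0.05. Chance would give 594 such genes here. In the sums that follow it would give 495 in macrophage-like, 429 in monocyte-like, 452 in CD8 T-like and 165.5 in NK-like cells. For type 2 dendritic, regulatory T-like, type 1 dendritic, plasmacytoid dendritic and melanoma-like cells it would give 222, 198, 262, 74.75 and 537. DESeq2 called 2, both lower, Chil3 (adjusted p = 0.01) and Fdps (adjusted p = 0.0126). The groups' ranges did not overlap for 7.18% of the genes, where chance gives 10%. Nor did any of the 10 genes followed throughout pass, the widest estimates being 0.76 ± 0.29 for Nos2, the inducible nitric oxide synthase, 0.53 ± 0.40 for Arg1, arginase, and -0.45 ± 0.28 for Cxcl10, an interferon-induced T cell chemokine. Ifng (0.28), Mrc1 (0.25), Cd274, which encodes PD-L1 (0.22), Pdcd1, which encodes PD-1 (0.11), Gzmb (-0.07) and Cxcl9 (-0.13) lay nearer 0.

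Among the 22 lists tested in the all-immune sum, 6 passed with the preset correlation, and for all 6 the adjusted p = 0.98 with an estimated correlation. No member of any of them passed the gene test, nor any member adjusted over the list alone. The type I interferon response, antiviral genes induced by interferon alpha and beta, was lower (31 of 34 members lower, median log2 fold change -0.15, adjusted p = 4.05e-05), with Oas1g at -0.56 ± 0.22 and Oas1a at -0.46 ± 0.22, both sensors of double-stranded RNA. The regulatory T cell suppressive list was lower (15 of 21 members, adjusted p = 0.0191), with the chemokine receptor Ccr8 at -1.01 ± 0.31 and Tnfrsf4, which encodes OX40, at -0.36 ± 0.15. Regulatory T-like cells averaged 3.13% and 2.50% of named immune cells, with 1.76% in TBK1 replicate 4, and within their own sum this list leaned higher without passing (adjusted p = 0.505). The cytotoxic effector list was higher (23 of 27 members, granzyme gene Gzma 0.52 ± 0.24, Lamp1 0.28 ± 0.17). So was the naive or memory T cell list (14 of 18, Dapl1 0.98 ± 0.33, Xcl1 0.66 ± 0.26), while the unnamed cluster led by Xcl1 and Tcf7 averaged 4.32% and 6.02% of the immune cells. Proliferation was lower (28 of 34; Tyms -0.22 ± 0.15, Tuba1b 0.17 ± 0.09) and the complement and lipid-associated macrophage list higher (24 of 26; Gpnmb 0.88 ± 0.43, Ctsd 0.39 ± 0.20), each of these 4 at an adjusted p of 0.0463. The shares of CD8 T-like, NK-like and macrophage-like cells, which enter this sum, also averaged higher in the TBK1 group, none past the threshold. The neutrophil RNA list had a median of 0.81 and did not pass (adjusted p = 0.0820), with the neutrophil-like share of TBK1 replicate 4 at 2.91%. Without TBK1 replicate 4 the proliferation list was higher (adjusted p = 0.00643), the complement and lipid-associated list lower (adjusted p = 0.00838), and the naive or memory T cell and suppressive lists no longer passed (0.294 and 0.275). The other libraries mattered too: the type I interferon call ended without control replicate 2 (0.301) or TBK1 replicate 3 (0.520). The unnamed myeloid cluster led by Ifit1 and Rsad2, members of this list, held 6.98% of the immune cells in control replicate 2, 1.46% in TBK1 replicate 3 and 3.26% to 3.90% in the other 4 libraries. Further, each of the other 5 ended without at least 1 further library, at an adjusted p of up to 0.986. These 5 lists also ended under at least 1 other setting, the shared matrix as TBK1 among them for all 5 (adjusted p of 0.0540 to 0.254). The remaining 16 lists had adjusted p values from 0.0820 to 0.960. They included T cell exhaustion, checkpoint ligands and co-stimulation, cell death, oxidative phosphorylation, melanoma pigment RNA and fibroblast and endothelial RNA, none of which passed in any immune sum, and 2 of their members passed adjusted over the list alone. The erythroid list had too few detected members to test.

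Macrophage-like cells, the deepest myeloid class (796 to 1881 cells and 2516375 to 8824642 UMIs per library), had higher antigen presentation lists in the TBK1 group. The MHC class II presentation list was higher (9 of 10 members, median 0.28, adjusted p = 0.00177; adjusted p = 0.79 with an estimated correlation) and passed without each library in turn. It ended under the stricter cell filter (adjusted p = 0.506) and with the shared matrix as control (0.2405). Its transcriptional master regulator Ciita, also in the interferon gamma list, stood at 21.8 ± 2.02 CPM in the control and 38.3 ± 7.23 in the TBK1 group (0.80 ± 0.17, n = 3), and H2-Aa, a class II chain, at 0.42 ± 0.17. Ciita passed adjusted over the list alone in both lists and not over all genes. The interferon gamma response was higher (21 of 31 members, the GTPase gene Gbp5 0.51 ± 0.18, adjusted p = 0.00507), and so was MHC class I presentation (18 of 20, H2-T23 0.41 ± 0.11, peptide transporter Tap2 0.32 ± 0.12, adjusted p = 0.00507). The inflammatory (M1-type) list was higher (16 of 20, scavenger receptor Marco 1.84 ± 0.47, Nos2 0.59 ± 0.26, adjusted p = 0.00867). The NF-kappaB and TNF response was higher too (28 of 32, Birc3 0.39 ± 0.14, adhesion molecule Icam1 0.33 ± 0.12, adjusted p = 0.0245). Proliferation was lower (31 of 34 members, median -0.30, adjusted p = 2.55e-05), with the replication helicase genes Mcm2 at -0.40 ± 0.17 and Mcm6 at -0.45 ± 0.20. For these 5 lists the adjusted p lay between 0.79 and 0.82 with an estimated correlation, with no other member past the test over the list alone.

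No gene passed in macrophage-like cells. By edgeR 0 of 9905 were called, with 370 at an unadjusted p under 0.05. DESeq2 called 1, Mid1, a ubiquitin ligase gene (2.09 ± 0.37 in edgeR), and ranges were apart for 8.74% of genes, where chance gives 10%. Next in line were Igf1, a growth factor made by tissue macrophages (0.85 ± 0.18), and, lower, the heat shock gene Hspa1a (-0.61 ± 0.13) and the TGF-beta family ligand gene Gdf3 (-0.59 ± 0.13). Without control replicate 3 the proliferation (0.0941), interferon gamma (0.717), class I (0.0758), M1-type (0.386) and NF-kappaB (0.837) lists no longer passed. Without TBK1 replicate 4 the proliferation (0.964), class I (0.0511), M1-type (0.472) and NF-kappaB (0.478) lists ended, and without control replicate 2 the class I list (0.101). None of the 5 higher lists passed under the stricter cell filter (adjusted p of 0.216 to 0.984), and with doublets kept only the class II list did, with proliferation at 0.0667. With the shared matrix as control the interferon gamma list ended (0.178), with it as TBK1 the M1-type (0.0556) and NF-kappaB lists (0.0981), and at the 20% mitochondrial limit the NF-kappaB list (0.0543). In TBK1 replicate 4, 81.5% of the macrophage-like cells belonged to the cluster with Arg1, Mmp12 and Nos2, against 42.2% to 63.3% in the other libraries.

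Monocyte-like cells showed the lowest adjusted p of any list in an immune class, for a lower type I interferon response in the TBK1 group. Of its 32 measured members 31 were lower, with a median of -0.27 (adjusted p = 1.77e-10; adjusted p = 0.79 with an estimated correlation), 0 passed over all genes and 5 passed adjusted over the list alone. Oasl1, a 2′-5′-oligoadenylate synthetase-like gene, stood at 78.7 ± 6.64 CPM in the control and 50.03 ± 7.84 in the TBK1 group (-0.63 ± 0.14, n = 3), and the nucleotide kinase gene Cmpk2 at 28.3 ± 6.71 and 14.1 ± 2.77 (-1.01 ± 0.23). The list passed without each library in turn (adjusted p of 2.07e-11 to 3.51e-06). Myeloid-recruiting chemokines were lower (11 of 15, adjusted p = 0.0364, 3 adjusted over the list alone), with the CCR2 ligands Ccl7 at -0.67 ± 0.14 and Ccl12 at -0.66 ± 0.15. Also lower at an adjusted p of 0.0342 were the complement and lipid-associated list (16 of 26 members, 1 adjusted over the list alone; cathepsin gene Ctsl -0.54 ± 0.17) and the immediate early and heat shock list (19 of 23, 0 adjusted over the list alone; phosphatase gene Dusp1 -0.35 ± 0.11, Dnaja1 -0.39 ± 0.14). The last of these holds genes that tissue dissociation induces. MHC class II presentation was higher at the same adjusted p (10 of 11, 0 adjusted over the list alone), with H2-Aa at 0.32 ± 0.14 and, against the direction, Lgmn at -0.22 ± 0.10. With an estimated correlation the adjusted p = 0.79 for each of these 4 lists.

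For single genes in monocyte-like cells (1225982 to 3442202 UMIs per library), edgeR called 0 of 8577, with 519 at an unadjusted p under 0.05, and 12.3% of genes had ranges apart, where chance gives 10%. Spp1, which encodes osteopontin, stood at 787 ± 202 CPM in the control and 352 ± 59.9 in the TBK1 group (-1.16 ± 0.18, adjusted p = 0.233), and Rsrp1 at -0.72 ± 0.15. Pecam1, an adhesion molecule of endothelium and leukocytes (1.00 ± 0.17), and Spic, a transcription factor of iron-recycling macrophages (1.54 ± 0.27), leaned the other way. DESeq2 called 3 of these, Spp1, Rsrp1 and Spic. Without control replicate 3 edgeR called 45 genes and the 4 lists after the type I interferon response no longer passed (0.284 to 0.482). Without control replicate 4 it called 2 genes, and the complement and immediate early lists no longer passed (0.102 and 0.0767). Without TBK1 replicate 4 the class II (0.226) and immediate early (0.0664) lists were lost, and without TBK1 replicate 3 the complement (0.131), chemokine and immediate early lists (0.209 for both). Lost as well were, without TBK1 replicate 2, the complement (0.338) and chemokine lists (0.789) and, without control replicate 2, the chemokine list (0.159). The cluster with Ly6i, Ccl12 and Il1b made up 71.1%, 43.5% and 66.6% of the monocyte-like cells of control replicates 2, 3 and 4 and 48.4%, 47.0% and 52.3% of those of TBK1 replicates 2, 3 and 4. The cluster with Ace and Treml4 made up 13.4%, 32.9% and 17.8%, and 33.8%, 38.8% and 29.6%. With doublets kept these 4 lists ended (0.0793 to 0.776), as under 2 or 3 further settings each. Among these settings, replicate number as a block ended the complement (0.06335), chemokine (0.0676) and immediate early lists (0.06335). The type I interferon call held in all settings but the estimated correlation and fry.

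In CD8 T-like cells 1 gene changed: Serpine2 (ENSMUSG00000026249, chromosome 1, 79794197 to 79861180), a secreted serine protease inhibitor, fell from 145 ± 15.4 CPM in the control to 84.5 ± 5.81 in the TBK1 group (log2 fold change -0.78 ± 0.11, adjusted p = 0.0180, n = 3 per group). The chemokine receptor gene Ccr2 (43.5 ± 11.8 and 80.7 ± 9.01 CPM, 0.90 ± 0.16, adjusted p = 0.0776) and Malt1, a signalling protease of antigen receptors (0.57 ± 0.11), had the lowest p on the other side without passing, and the histone gene Hist1h2ap stood at -0.85 ± 0.20. The cytotoxic effector list was higher (19 of 25 members, median 0.15, adjusted p = 0.0180; adjusted p = 0.79 with an estimated correlation), with 0 members past the test over all genes or adjusted over the list alone. Its members included Gzma (1.02 ± 0.29) and Ifng (0.26 ± 0.11, 237 ± 28.0 and 284 ± 13.9 CPM), while Gzmb stood at -0.09 ± 0.11 and Pdcd1 at 0.13 ± 0.12. The naive or memory T cell list did not pass (adjusted p = 0.0656), although 2 of its 10 members did when adjusted over the list alone. Over 9032 genes edgeR called 1, with 420 at an unadjusted p under 0.05. DESeq2 called 2, Serpine2 and Ccr2, and ranges were apart for 9.19%, where chance gives 10%. Serpine2 passed without control replicate 3 (adjusted p = 0.000700, among 4 genes), and not without control replicate 2 (0.0932) or 4 (0.0603) or TBK1 replicate 2 (0.478), 3 (0.0865) or 4 (0.109). Other genes called, named after their values were seen, were Ccl9 without control replicate 2, Ccr2 and Ly6c2 without control replicate 4, and Prss2 and Trbc1 without TBK1 replicate 4. Over all alternatives Serpine2 passed in 6 of 17 (adjusted p of 2.22e-07 to 1.00), and it ended with the shared matrix as control (0.0579) or as TBK1 (0.173, where Ccr2 was called instead), all 8 labels, the stricter filter (0.1605), the 20% mitochondrial limit (0.195) or the granzyme-high cluster counted as CD8 T-like (0.953). Serpine2 was among the 10 leading genes of that unnamed granzyme-high cluster, which had Cd8a in 91.9% of its cells. The Serpine2 call therefore depends on where the CD8 T-like class ends. The cytotoxic list ended without control replicate 2 (0.301) or TBK1 replicate 4 (0.174), under the stricter filter (0.137) and with the shared matrix as TBK1 (0.0756). Ccl5, Klrd1 and Nkg7, members of this list, were among the leading genes of a CD8 T-like cluster. That cluster made up 48.6%, 46.1% and 58.9% of the CD8 T-like cells of control replicates 2, 3 and 4. In TBK1 replicates 2, 3 and 4 it made up 58.7%, 60.9% and 57.3%. The list was not tested within clusters, so this makeup stays open. The real grouping called 1 list in CD8 T-like cells, and the other splits 2 to 9.

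In NK-like cells (115 to 221 cells per library) no gene and no list changed. Gzmg, a granzyme gene of activated killer cells, averaged 23.1 ± 36.9 CPM in the control and 909 ± 860 in the TBK1 group (log2 fold change 5.31 ± 1.03, adjusted p = 0.196), with a spread in each group close to or above its mean and overlapping ranges. Pcif1 (1.26 ± 0.31) was higher, and Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, was lower at 211 ± 43.0 and 106 ± 11.3 CPM (-0.98 ± 0.22), as was Epb41 (-0.92 ± 0.26), none past the threshold. Pdcd1 stood at 0.75 ± 0.36, Gzmb at 0.17 ± 0.15 and Ifng at 0.08 ± 0.37. With edgeR 0 of 3310 genes passed, with 109 at an unadjusted p under 0.05 and 8.37% with ranges apart (10% by chance). DESeq2 called 0. Without TBK1 replicate 2 edgeR called 5, all higher: Gzmg (5.90, adjusted p = 4.57e-13), Gzmd, Gzme, Spp1 and Ifitm1. At the 20% mitochondrial limit edgeR called 1. All 15 lists missed the threshold (adjusted p of 0.150 to 0.803).

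In type 2 conventional dendritic cells, which present antigen to CD4 T cells, Retnla (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461), a secreted marker of alternative activation, rose from 49.6 ± 39.8 CPM in the control to 442 ± 194 in the TBK1 group (log2 fold change 3.00 ± 0.42, adjusted p = 0.0102, n = 3 per group). Interferon-responsive genes were lower as lists. The type I response was lower in 25 of 28 members (median -0.30, adjusted p = 0.000218; Isg15 -0.61 ± 0.18, Ifi204 -0.61 ± 0.19), and the interferon gamma response in 23 of 28 (median -0.34, adjusted p = 0.000243; the GTPase gene Iigp1 -0.81 ± 0.22, the dendritic cell transcription factor Irf8 -0.47 ± 0.16). Both passed without each library in turn, with 0 members past the test over all genes or adjusted over the list alone, and with an estimated correlation their adjusted p = 0.59 and 0.48. The alternatively activated (M2-type) macrophage list was higher (11 of 17 members, adjusted p = 0.0186, 1 rose over all genes, Retnla, and 6 adjusted over the list alone), with Arg1 at 1.54 ± 0.36 and the matrix gene Fn1 at 152 ± 79.1 and 367 ± 53.0 CPM (1.22 ± 0.25). The complement and lipid-associated list was higher too (15 of 20, adjusted p = 0.0270; Apoe 1.01 ± 0.30, C3 0.89 ± 0.32). Lower were the NF-kappaB and TNF response (21 of 28, adjusted p = 0.0186; Gadd45b -0.47 ± 0.16, Tnf -0.91 ± 0.36) and proliferation (15 of 18, adjusted p = 0.0107; Stmn1 -0.60 ± 0.22, Pclaf -0.71 ± 0.26), with 0 members of these 3 lists adjusted over the list alone. For these 4 lists the adjusted p lay between 0.48 and 0.69 with an estimated correlation. The M2-type and complement lists hold macrophage genes, such as Arg1, detected in 60.1% of the cells of a macrophage-like cluster. RNA of macrophage-like cells in these sums was not tested.

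Other low-p genes in these dendritic cells were Ifitm1, an interferon-induced membrane protein gene (-0.77 ± 0.19), and the biliverdin reductase gene Blvra (-0.94 ± 0.25), and Cxcl9 stood at -0.47 ± 0.16. Of 4432 genes edgeR called 1, with 184 at an unadjusted p under 0.05, and 9.70% had ranges apart (10% by chance). DESeq2 called 1, Fn1, and not Retnla (adjusted p = 1.00). Retnla passed in 11 of 16 alternatives (adjusted p of 3.67e-40 to 1.00), ending also with the shared matrix as control (log2 fold change 1.58) and with all 8 labels (1.54), and it stood at 1.03 at the 20% mitochondrial limit. The call ended without control replicate 2 (adjusted p = 0.0502) or TBK1 replicate 3 (0.0538), each leaving 0 genes, and 3, 3 and 4 genes were called without control replicate 3, control replicate 4 and TBK1 replicate 4. The 4 lists other than the interferon lists each ended without 1 library or more. The M2-type list ended without control replicate 3 (0.240), TBK1 replicate 3 (0.269) or TBK1 replicate 4 (0.0798), and proliferation without control replicate 3 (0.120). The complement list ended without control replicate 2 (0.285), control replicate 4 (0.117) or TBK1 replicate 4 (0.818), and NF-kappaB without any 1 of control replicates 2, 3 and 4 (0.0710, 0.248 and 0.117) and TBK1 replicates 2 and 3 (0.144 and 0.269). Each of these 4 also ended under 2 to 4 other settings, the stricter filter (M2-type 0.172, proliferation 0.678), doublets kept (complement 0.177) or the 20% mitochondrial limit (NF-kappaB 0.876) among them, and both interferon lists held. In these sums of 81 to 159 cells, control replicate 3 held the lowest Retnla, 3.85 CPM.

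In regulatory T-like cells genes of MHC class II, the antigen-presenting complex of B cells, dendritic cells and macrophages, fell in the TBK1 group. H2-Eb1 (chromosome 17, 34305867 to 34316674) fell by 2.12 ± 0.39 on the log2 scale, from 113 ± 41.0 to 26.8 ± 21.8 CPM (adjusted p = 0.0238, n = 3 per group), H2-Ab1 by 1.58 ± 0.31 (adjusted p = 0.0238) and H2-Aa by 1.78 ± 0.37 (adjusted p = 0.0476). The MHC class II list was lower (5 of 5 members, 3 fell over all genes and 4 adjusted over the list alone, adjusted p = 1.94e-06; adjusted p = 0.78 with an estimated correlation). It passed without each library in turn, and ended with doublets kept (adjusted p = 0.188), at the 20% mitochondrial limit (0.632) and with the shared matrix as TBK1 (0.0905). The immunoglobulin constant gene Igkc (chromosome 6, 70726435 to 70726966) fell from 474 ± 741 to 18.0 ± 7.43 CPM (-4.73 ± 0.91, adjusted p = 0.0238). These 4 are genes of other cell types, and they were read in sums of 74 to 120 cells. The 3 MHC genes together had 226, 97 and 80 UMIs in control replicates 2, 3 and 4, and 27, 31 and 22 in TBK1 replicates 2, 3 and 4. Between 54.5% and 83.8% of them came from the 5 highest cells of a library. Hcst, an adaptor of NK receptors (0.74 ± 0.20), and the calcium-binding S100a4 (0.54 ± 0.15) were higher without passing, and Gzmb (0.29 ± 0.16) and Pdcd1 (-0.08 ± 0.18) did not pass. Of 3967 genes edgeR called 4, all lower, with 180 at an unadjusted p under 0.05 and 9.71% with ranges apart (10% by chance), and DESeq2 called 0. Without control replicate 2, TBK1 replicate 2 or TBK1 replicate 4 edgeR called 0 genes, and without TBK1 replicate 3 it called 1, H2-Eb1; Igkc stood at -1.36 without control replicate 2. Over all alternatives H2-Eb1 passed in 8 of 16, H2-Ab1 in 7 of 16, H2-Aa in 5 of 16 and Igkc in 6 of 13.

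In type 1 conventional dendritic cells, which cross-present tumour antigen to CD8 T cells, no gene passed and the hypoxia and glycolysis list was lower in the TBK1 group (19 of 21 members, median -0.31, adjusted p = 2.83e-05, 0 over all genes and 3 adjusted over the list alone). Its members included Pkm, pyruvate kinase, at 662 ± 18.3 and 506 ± 14.1 CPM (-0.39 ± 0.11, n = 3), and the lactate exporter gene Slc16a3 at 45.9 ± 2.13 and 24.2 ± 3.81 CPM (-0.95 ± 0.27). This list passed without each library in turn, while its adjusted p = 0.51 with an estimated correlation, as for the other 4 lists that passed. Complement and lipid-associated genes were lower (12 of 16, adjusted p = 0.00124, 7 adjusted over the list alone), with the lipid carrier Apoe at 65.5 ± 5.09 and 23.3 ± 13.6 CPM (-1.39 ± 0.32) and Ctsb at -0.60 ± 0.16. Cytotoxic genes (10 of 15, perforin gene Prf1 -0.94 ± 0.37, Klrd1 -1.14 ± 0.46) and suppressive genes (10 of 12, Gzmb 268.5 and 127 CPM, Tnfrsf9 -0.98 ± 0.56) were lower. MHC class II genes were higher (10 of 12, Ciita 0.40 ± 0.17, Lgmn -1.10 ± 0.36), these 3 lists at an adjusted p of 0.0349 with 0 members adjusted over the list alone. The cytotoxic genes are those of lymphocytes. Cd8a, which type 1 dendritic cells also express, and Cd3e, which they do not, were detected in 24.2% and 13.5% of the cells of the larger cluster (median 5486 UMIs), against 4.00% and 2.75% of melanoma-like cells (median 19595 UMIs), which should lack both.

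Among single genes of type 1 dendritic cells, Cebpb, a myeloid transcription factor, stood at 166 ± 19.7 and 82.7 ± 23.3 CPM (-0.96 ± 0.20), and Colgalt1 (0.95 ± 0.17) and St3gal5 (0.97 ± 0.21), both enzymes of glycosylation, were on the other side. By edgeR 0 of 5231 genes passed, with 263 at an unadjusted p under 0.05 and 10.5% with ranges apart (10% by chance). DESeq2 called 0, and 1 was called without control replicate 2 and 1 without control replicate 3. The complement list ended without control replicate 3 (0.124). Without control replicate 2, control replicate 4 or TBK1 replicate 2 the class II list (0.377, 0.0689, 0.324), the cytotoxic list (0.358, 0.148, 0.816) and the suppressive list (0.2501, 0.148, 0.719) ended, and without TBK1 replicate 3 the cytotoxic list (0.184). Under the stricter filter these 4 lists ended (0.255 each), as under 1 to 5 further settings, and the hypoxia and glycolysis list held.

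In plasmacytoid dendritic cells, the main makers of type I interferon in viral infection, no gene passed, and the complement and lipid-associated macrophage list was lower in the TBK1 group (10 of 11 members, median -0.78, adjusted p = 0.00411, 0 over all genes and 5 adjusted over the list alone; adjusted p = 0.75 with an estimated correlation). Lgals3, which encodes galectin-3, stood at 774 ± 416 and 346 ± 69.5 CPM (-1.19 ± 0.32, n = 3) and the complement gene C1qb at 405 ± 345 and 78.1 ± 64.1 (-2.46 ± 0.65), both abundant in macrophages. C1qa was detected in 4.91% of these cells (median 1600 UMIs) and in 3.19% of NK-like cells (median 1172 UMIs), which should lack it. On the other side Ikbkb, a kinase of the NF-kappaB pathway (0.80 ± 0.30), and the translation factor gene Eif3i (0.80 ± 0.30) did not pass. Of 1495 genes edgeR called 0, with 51 at an unadjusted p under 0.05 and 8.49% with ranges apart (10% by chance), and DESeq2 called 0. Without control replicate 3, control replicate 4 and TBK1 replicate 3 edgeR called 1, 15 and 1. At the 20% mitochondrial limit, a setting added after the data were seen, the list was higher (adjusted p = 0.0376), and with doublets kept it ended (0.519). It also ended without control replicate 2 (0.207) or control replicate 3 (0.0686), and these sums are the smallest, at 31 to 54 cells per library.

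Over the 9 immune sums, 31 of 163 list tests passed with the preset correlation, 13 higher and 18 lower. Of these 31, 6 passed without each library in turn: type I interferon response in monocyte-like and type 2 dendritic cells, interferon gamma response in type 2 dendritic cells, MHC class II in macrophage-like and regulatory T-like cells, and hypoxia and glycolysis in type 1 dendritic cells. Of these 6, 4 also passed in all other settings of cells and scaling, the MHC class II lists being the exceptions. With an estimated correlation, and with fry, 0 of the 163 passed. Median, mean and test had the same sign for each of the 31. The real grouping stands out little by this count: of the 10 ways to split the 6 libraries 3 against 3, 9, the real one included, gave 31 lists or more, and the highest gave 59. Other splits were not tested without each library or in other settings, so how many lists would hold under a wrong grouping is unknown. Lists that passed in 1 class and not in another were not tested for a difference between classes.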

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

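The tests of marker-free regulatory T-like cells, of single libraries for the monocyte-like interferon list and of other splits for the class shares were chosen only after the result was seen.

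In melanoma-like cells, where the report tests Tbk1 alone and further genes follow under the other observations, edgeR called 58 of 10739 genes, 30 higher and 28 lower in the TBK1 group, a signal in cells that the enrichment for CD45 was meant to leave out. The count was 0 with the shared matrix as control or with all 8 labels, 98 with that matrix as TBK1, and 15 to 66 without 1 library. All 8 labels place the same matrix in both groups, so a loss of calls there is partly built in. RNA of immune cells was weighed as a technical cause: the fixed immune markers had a median log2 fold change of -0.0612 in these sums, and 11 of the 58 genes (19.0%) were higher in immune cells, both of which speak against it. Depth was weighed as well: with every sum thinned to 2660237 UMIs, 40 genes were called, 31 of them shared with the 58. Uneven depth alone is therefore unlikely to account for the count. Of the 58, 57 kept their sign, which tests little because the thinned counts are drawn from the same counts. The edited tumour genome is the biological explanation the design gives. However, 2 of the 58 genes were also lower by DESeq2 in immune cells, which were not edited. These were Fdps in all immune cells (-0.70) and Rsrp1 in monocyte-like cells (-0.73), and edgeR called neither there. In all immune cells Cxcl9 and Tbk1 leaned against their direction in melanoma-like cells. Changes shared by tumour and immune cells were not weighed. Per the labels each group carries a single guide RNA, so other effects of that guide cannot be told apart from loss of Tbk1. With 3 libraries per group a difference between tumours of another origin also stays open.

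The lower MHC class II genes of regulatory T-like cells were weighed against RNA or attached material of antigen-presenting cells. Over cells without a UMI of another type's marker the median log2 fold change of H2-Aa, H2-Ab1 and H2-Eb1 was -0.579, against -1.78 over all cells, so most of the difference may lie in cells that carry such RNA, although H2-Eb1 alone remained at -1.29 ± 0.44. The 22 cells with at least 3 UMIs of the 3 genes held a marker UMI in 59.1% of cases, against 22.6% in the 566 others. Their depth differed too, with a median of 4667 UMIs against 2033. Scaled for depth, the 22 cells held 3.06 marker UMIs per 10000 UMIs and the others 1.10. The summed markers of B-like, type 1, type 2 and plasmacytoid dendritic and macrophage-like cells averaged lower in the TBK1 group (log2 ratios of -0.292 to -0.071). Those of mature migratory dendritic cells averaged higher (0.147). None differed beyond its spread (exact p of 0.4 to 1). These sums include markers over 5 CPM in CD8 T-like cells, and the smallest possible exact p is 0.1, so they cannot decide the question. A stricter marker set of 79 genes left only 14 cells and was void, and was replaced after that was seen by the 54 markers under 5 CPM in CD8 T-like cells.

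The lower type I interferon list of monocyte-like cells was weighed against 3 technical causes. For the makeup of the class the outcome is open: the list was lower in all 3 clusters (medians -0.20, -0.22 and -0.13, adjusted p = 4.79e-05, 0.000404 and 0.0296 with the preset and 0.531 to 0.957 with an estimated correlation), against -0.27 in the class. None was as low as the class, and 1 reached the 75% of its median that had been asked of at least 2. A single library does not account for it, since the highest adjusted p without 1 library was 3.51e-06, and RNA of melanoma-like cells would bring 0.110% of the difference for the median gene, far too little. The unnamed myeloid cluster led by Ifit1 and Rsad2 also has Oasl1 and Cmpk2 among its leading genes. It was left out of the class because its macrophage and monocyte scores, 1.01 and 0.88, were too close. It held 6.98% of immune cells in control replicate 2 and 1.46% in TBK1 replicate 3. Neither this class boundary nor RNA of that cluster was tested for the list. The call rests on the preset correlation, and a biological explanation, the TBK1 guide in the tumour, was not separated from differences between mice.

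With 10 splits of the 6 libraries, there are too few for a share under 0.05, whatever the count. The real count and the highest count of another split were 0 and 0 for genes in all immune cells, 0 and 1 in macrophage-like, 0 and 41 in monocyte-like, 1 and 4 in CD8 T-like, 0 and 4 in NK-like and 1 and 4 in type 2 dendritic cells. They were 4 and 8 in regulatory T-like, 0 and 19 in type 1 dendritic, 0 and 10 in plasmacytoid dendritic and 58 and 6 in melanoma-like cells, 0 and 0 for class shares and 31 and 59 for gene lists of the immune sums. For gene lists of melanoma-like cells they were 2 and 13. Splits with a count at least as large, the real one included, numbered 10 for all immune, macrophage-like, monocyte-like, NK-like, type 1 dendritic and plasmacytoid dendritic genes and for shares, 5 for CD8 T-like cells, 4 each for type 2 dendritic and regulatory T-like cells, 9 for lists of the immune sums and 1 for melanoma-like genes. The counts of 41 and 19 come from the same split, control replicates 2 and 4 with TBK1 replicate 4 against the rest. Those libraries also had the highest shares of the macrophage-like cluster with Arg1, 60.2%, 63.3% and 81.5% against 42.2% to 54.8%. They likewise had the highest shares of the monocyte-like cluster with Ly6i, 71.1%, 66.6% and 52.3% against 43.5% to 48.4%. The clusters of type 1 dendritic cells did not divide this way, and a cause of the counts was not tested.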

How the results depend on the processing

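Over alternatives, 346 of 432 values of shares, ratios, counts and Tbk1 levels kept direction and side of the threshold, or a count within 1.5 times. Of 526 values of gene lists that had passed, 314 still passed in the same direction, 209 did not and 3 turned. Named genes, of which 17 of 160 passed in the comparison itself, gave 2537 values: 2258 kept sign and side, 100 changed sign without passing, and 179 changed side. The looser mitochondrial limit, the granzyme-high cluster counted as CD8 T and all settings for melanoma-like cells were added after the data were seen. For shares, mature migratory DC passed with the shared matrix as control (-1.25, adjusted p = 0.0302) and with the stricter filter (-1.785, adjusted p = 0.0241), and neutrophil with the shared matrix as control (3.35, adjusted p = 0.0302) and with replicate number as a block (2.34, adjusted p = 0.0238). Signs turned for cDC1 (0.0745) and cDC2 (0.0229) with TMM factors over the classes, and for cDC2 (0.0467) at a mitochondrial limit of 20%, none past the threshold. Leaving out 1 library gave log2 fold changes of -1.78 to -0.99 for mature migratory DC, -0.64 to -0.35 for monocyte, 0.92 to 3.55 for neutrophil, 0.04 to 0.54 for CD8 T, 0.06 to 0.46 for macrophage, -0.0535 to 0.65 for B, -0.37 to 0.10 for cDC2, -0.39 to 0.0145 for pDC and -0.12 to 0.22 for the Tbk1 level in all immune cells. The macrophage share of macrophage and monocyte cells differed by 9.51 to 18.3 points without 1 library and by 6.66 with doublets kept, and the log2 ratio of CD8 T to regulatory T cells by 0.38 to 0.68 without 1 library. Counts of genes without 1 library ran over 0 to 45 in monocyte, 0 to 4 in CD8 T, 0 to 5 in NK, 0 to 4 in cDC2, 0 to 6 in regulatory T, 0 to 1 in cDC1, 0 to 15 in pDC and 15 to 66 in melanoma-like cells, and lists over 25 to 39. DESeq2 called 2 genes in all immune, 1 in macrophage, 3 in monocyte, 2 in CD8 T and 0 in regulatory T cells. With no filter on low counts, which tests more genes, 23 were called in macrophage, 71 in monocyte, 38 in CD8 T, 13 in NK, 34 in cDC2, 8 in regulatory T, 47 in cDC1, 27 in pDC and 307 in melanoma-like cells. With replicate number as a block the counts were 1 in macrophage, 9 in CD8 T, 1 in pDC and 99 in melanoma-like cells; libraries of equal number correlated at -0.220 to 0.339 over the 10 sums and at -0.381 to -0.305 in shares, all numbers lay over 0.1 in 0 sums, and at most 3 of 6 libraries of a sum (melanoma-like) correlated best with their own number, so the number is not treated as a pair. With the shared matrix as TBK1 the counts were 1 in monocyte, 1 in regulatory T and 98 in melanoma-like cells and 18 lists; with it as control 0 in CD8 T, 0 in cDC2 and 0 in melanoma-like cells; with all 8 labels 0 in CD8 T, cDC2, regulatory T and melanoma-like cells. Tbk1 in melanoma-like cells was -1.24 with the shared matrix as control (adjusted p = 0.845), -1.20 with all 8 labels (adjusted p = 1.00) and -1.69 to -1.31 without 1 library, and none of these values was used to assign that matrix to a group. The stricter filter gave 1 gene in monocyte, 0 in CD8 T, 2 in cDC2 and 15 lists; doublets kept gave 2 in CD8 T and 0 in regulatory T; the 20% limit gave 0 in CD8 T, 1 in NK, 6 in cDC2, 0 in regulatory T and 38 in melanoma-like cells; the granzyme-high cluster counted as CD8 T gave 0 in CD8 T. An estimated correlation and fry each left 0 lists. Without 1 library the adjusted p ran from 6.24e-06 to 0.803 for proliferation in all immune cells (turned at 0.00643) and from 8.24e-05 to 0.386 for complement and lipid-associated macrophage in all immune cells (turned at 0.00838), and complement and lipid-associated macrophage in pDC turned at the 20% limit (adjusted p = 0.0376). Apart from the filter on low counts, the cause of these changes was not tested. The stricter filter was not run for pDC or melanoma-like cells, which had too few cells. Depth limits the plasmacytoid dendritic sums most, at 69381 to 106143 UMIs.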

Other observations

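The tests in melanoma-like cells and in single clusters were chosen only after the clusters had been seen. Melanoma-like cells of the TBK1 group had higher Lmo1, a transcription cofactor, at 16.2 ± 2.49 CPM in the control and 36.5 ± 0.972 in the TBK1 group (log2 fold change 1.16 ± 0.12, adjusted p = 0.000972, n = 3 per group). Fxyd1, a regulator of the sodium pump, rose by 1.33 ± 0.15, Cxcl9, an interferon gamma-induced T cell chemokine, by 1.26 ± 0.15 from 9.46 ± 1.34 to 21.9 ± 1.36 CPM, and Ddit4l, an inhibitor of mTOR signalling, by 0.85 ± 0.15. Hspa1b, a heat shock gene, fell (-1.70 ± 0.25, adjusted p = 0.00711), as did Kcnn4, a potassium channel gene (-0.76 ± 0.12, adjusted p = 0.0141). Hmgcs1, an enzyme of the sterol pathway, fell from 138 ± 9.95 to 81.9 ± 9.05 CPM (-0.76 ± 0.09, adjusted p = 0.00135). Fdps (-0.72 ± 0.09), Sqle (-0.55 ± 0.08), Msmo1 (-0.58 ± 0.10) and Cyp51 (-0.40 ± 0.08), further enzymes of that pathway, also fell; they were singled out after their values were seen and no fixed list covers them. Cxcl10 (-0.24 ± 0.13) and Cd274 (0.16 ± 0.15) did not pass.

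Proliferation was lower as a list in melanoma-like cells (32 of 34 members, 3 fell over all genes and 22 adjusted over the list alone, adjusted p = 1.06e-12; adjusted p = 0.48 with an estimated correlation), with the mitotic kinase genes Aurka (-0.61 ± 0.12) and Plk1 (-0.50 ± 0.10) and the kinesin gene Cenpe (-0.55 ± 0.11). It passed without each library in turn. The immediate early and heat shock list was lower too (16 of 22, 2 fell and 8 adjusted over the list alone, adjusted p = 0.0253; adjusted p = 0.94 with an estimated correlation), with Jun at 383 ± 36.4 and 227 ± 47.4 CPM, and was lost without control replicate 4 (0.122) or TBK1 replicate 3 (0.253). The immediate early and heat shock list also ended with the shared matrix as TBK1 (0.0531). The other 18 of 20 lists did not pass, type I interferon response lying nearest (adjusted p = 0.0652). The real grouping called 2 lists in these cells, and each other split of the 6 libraries called more, from 3 to 13. The number of lists therefore does not set the real grouping apart. edgeR called 58 of 10739 genes, with 1132 at an unadjusted p under 0.05 and 15.1% with ranges apart (10% by chance), and DESeq2 called 60, of which 43 were shared. Without control replicates 2, 3 and 4 the count was 18, 66 and 49, and without TBK1 replicates 2, 3 and 4 it was 15, 17 and 42. With the shared matrix as control, or with all 8 labels, it was 0, and with that matrix as TBK1 it was 98.

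Of the unnamed clusters, none differed in share past the threshold in edgeR. A cluster led by Ifit1, Rsad2 and Isg15, antiviral genes induced by interferon, in myeloid cells held 4.52% ± 2.13 of immune cells in the control and 2.89% ± 1.27 in the TBK1 group (SD, n = 3, adjusted p = 0.648). One led by Gzmf, Gzme and Gzmd, with Cd8a in 91.9% of cells, held 3.23% ± 1.79 and 4.02% ± 0.473 (adjusted p = 0.810), and one with Xcl1, Tcf7 and Lef1, genes of naive or memory T cells, 4.32% ± 1.501 and 6.02% ± 1.66 (adjusted p = 0.677). A cluster that mixes T cell and myeloid markers held 2.24% ± 1.38 and 0.813% ± 0.588 (log2 fold change -1.45, adjusted p = 0.162).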
